A study of Mus musculus with 18 samples.

How the data were processed

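The series holds 18 RNA-seq libraries of Thy1+ cells sorted from mouse hearts. Thy1 is a surface protein used to sort cardiac fibroblasts. The labels write the sorted population as Thy1+ HE or Thy1+HE- and do not spell out HE. The cells came from C57BL/6, C3H/HeJ and KK/HlJ mice that received saline (sham) or isoproterenol (ISO, an agonist of beta-adrenergic receptors) from implanted pumps. Cells of ISO hearts were taken at day 14 or day 21. The sham labels carry no day, so each strain's sham libraries served both days. Each of the 9 groups of strain and condition has 2 libraries. The labels give 2 per group and do not say whether these came from separate animals or pools, so p-values measure the spread between these libraries, which may be technical.

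Per the labels' protocols, cells were sorted into a lysis reagent, RNA was extracted, and mRNA libraries described as stranded were sequenced as single-end reads of 50 nt on an Illumina HiSeq instrument. Per the submitters' processing notes, the tools were FastQC, STAR 2.5.3a and edgeR, with the mm10 genome. The annotation release, the read counter and its strand setting are not given in the sources used here. The deposited values are raw read counts per Ensembl gene, whole numbers with a different total in each library, with no normalization by the authors. Reads of all strains were mapped to 1 genome build, which derives from C57BL/6, so a strain's variants can lower or move its counts. Without a stated strand setting, overlapping and antisense genes cannot be told apart. Genes with near-identical copies are reported as uncertain.

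Each library's table holds 53342 gene identifiers. Of these, 53237 matched the GENCODE M21 annotation, which gave symbols and coordinates on mm10, and the 105 others hold 0.0016% of reads. Totals ran from 7230741 to 26280685 counts. Floors cover counting error only, since the reads carry no molecular identifiers. The SE of a fold change was derived from the fold change and the F statistic of its edgeR test. It thus includes the spread between libraries. A gene was treated as at the floor at 3 counts per library or fewer. Levels are CPM, read counts scaled by edgeR's effective library sizes, and group means are given with the SD over 2 libraries. Sums over marker genes, Xist and the checks of libraries, with their 8712 genes, use CPM scaled by total counts alone. These carry no SD.

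The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, TMM scaling, robust fit) on the counts as deposited. All 18 libraries entered 1 fit with a term for each of the 9 groups, which leaves 9 residual degrees of freedom. Default filtering on the 9 groups left 15762 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in a comparison. The comparisons were ISO against sham in each strain and day, the mean of those differences over the 3 strains at each day, day 21 against day 14 in each strain, sham libraries between strains, and the difference in the ISO response between strains. These, the gene lists, the alternatives chosen beforehand and the rule for named genes were fixed before the data were examined.

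Named genes passed the test, had both libraries of one side above both of the other (for the means over strains, a change of the same sign in each of the 3 strains), reached a mean of 5 CPM on the higher side, and had neither a predicted or clone name nor a symbol ending in -ps. The largest changes were taken, up to 10 each way for the means, 5 each way within strains, and 3 each way for differences between responses. Up to 6 members of each list were added in order of adjusted p. Postn, Ltbp2, Col1a1, Col3a1, Acta2, Pdgfra, Tcf21 and Mki67 were reported whatever they showed. Ltbp2 was included because the group had studied it in these strains, so it is not an independent choice. Genes outside this rule are said to be chosen after their values were seen.

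The 37 gene lists cover matrix, fibroblast states, signalling, stress, metabolism and 14 sets of markers, and 34 had enough tested members. Each was tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and again with a correlation estimated from the data, adjusted over the lists of a comparison. Member counts are given over all genes tested and adjusted over the list alone. Lists share members, such as Ltbp2 and Sfrp2.

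Alternatives chosen beforehand were DESeq2 1.42.0, RLE scaling, no filter on low counts, the replicate number as a block, fits of only the groups compared, an estimated correlation, and each library left out in turn. Alternatives added after seeing the data were limma voom with library quality weights, a mean of at least 5 CPM, offsets for transcript length and GC content, and leaving out the 4 libraries with a median correlation to the others under 0.82, which leaves 1 library in each KK/HlJ group and in C3H/HeJ sham. A contrast averaging both days over the strains was also run after the data were seen; it called 9 genes, 8 higher and 1 lower, with 1054 at an unadjusted p under 0.05 (Cilp, Dkk3, Gm13889, Ltbp2, Pamr1, Postn, Prg4, Serpina3n and Sfrp2), and was not taken further. Fits with fewer libraries were first run with the filter derived again from the libraries left. After their counts were seen, the same 15762 genes were held in these fits. Counts of both versions are given for fits of only the groups compared and without the 4 divergent libraries. For each library left out in turn, the counts given are those with the genes held.

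The edgeR, DESeq2, voom, offset and camera steps were tested on simulated data, with 200 of 15762 genes changed, 2-fold or 4-fold; the other alternatives, the splits of the libraries and the search for copies were not. For the mean over strains at day 14, edgeR recovered 19% of the 2-fold and 72% of the 4-fold changes with 5 false among 96 calls, and voom 14% and 63% with 5 false among 82. DESeq2 recovered 30% and 85% but made 51 false calls among 166. The counts were drawn with edgeR's own estimates of spread, the same mean in all strains and no divergent libraries. The share of false calls in the real data was thus not measured for any method. The offsets gave 19% and 73% with 7 false among 99. These steps tested 14949 genes, or 14939 with offsets. For C3H/HeJ at day 14 (14991 genes tested, 14982 with offsets), edgeR recovered 2% and 19% with 2 false among 23 calls, DESeq2 6% and 39% with 42 false among 87, voom 1% and 13% with 0 false among 14, and the offsets 2% and 19% with 2 false among 23. Camera recovered 100% of 20 changed sets for the mean, and for C3H/HeJ 100% with the preset and 90% with the estimated correlation, with 0 false among 100 unchanged sets. The simulated genes were independent, so this does not test camera on correlated genes.

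Copies were sought by the share of 25-base words of a gene's transcripts found in another gene, with 50% as the threshold. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.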

Results

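RNA was sequenced from Thy1+ cells of hearts of C57BL/6, C3H/HeJ and KK/HlJ mice after saline (sham) or ISO, at day 14 or day 21 of pump infusion. Each of the 9 groups had 2 libraries. The title of the series asks how cardiac fibroblasts of different genetic backgrounds respond to ISO injury. Total counts of replicates 1 and 2 in C57BL/6 were 25356498 and 24748674 in sham, 16565460 and 14649066 at day 14, and 10453121 and 14871905 at day 21. Total counts of replicates 1 and 2 in C3H/HeJ were 12700814 and 19379717 in sham, 26280685 and 10469589 at day 14, and 11387682 and 21523501 at day 21. Total counts of replicates 1 and 2 in KK/HlJ were 12120730 and 10703774 in sham, 7230741 and 23832629 at day 14, and 20339795 and 8104823 at day 21. The 2 libraries of every group differed by more than counting noise, with a chi-square per degree of freedom between 59.0 and 158.5, and correlated at r = 0.761 to 0.936 over genes in log2 CPM. The median correlation with the other libraries was 0.783 for C3H/HeJ sham replicate 1, 0.789 for KK/HlJ sham replicate 1, 0.762 for KK/HlJ ISO day 14 replicate 1 and 0.813 for KK/HlJ ISO day 21 replicate 1, the 4 lowest values.

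Genes of resting fibroblasts were detected in every library. Pdgfra, a receptor on cardiac fibroblasts, stood at 639 ± 161, 455 ± 158 and 472 ± 256 CPM (SD, n = 2) in sham C57BL/6, C3H/HeJ and KK/HlJ. Tcf21, a transcription factor of cardiac fibroblasts, stood at 356 ± 9.03, 347 ± 61.6 and 399 ± 114 CPM. The 28 resting fibroblast genes summed to between 99226 and 145684 CPM. Markers of other cell types were lower and uneven. The 22 endothelial markers summed to 777.5 to 1828 CPM in 17 libraries and 3238 CPM in C3H/HeJ ISO day 21 replicate 1, which also had the highest sum of 22 macrophage and monocyte markers, 257.9 CPM. The 20 pericyte and smooth muscle markers ran from 1771 CPM in C57BL/6 ISO day 21 replicate 2 to 8937 CPM in C57BL/6 sham replicate 1. Mki67, a proliferation marker, stayed between 0 and 6.51 CPM in each library. Xist was found in every library, at 15.9 to 145.4 CPM, and Y-linked genes summed to 0 to 9 counts.

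At day 14, 6 genes rose on average over the 3 strains. Postn, a matricellular protein made by activated fibroblasts, rose by a log2 fold change of 2.38 (SE 0.233; edgeR adjusted p = 1.22e-05). It went from 361 ± 89.9 to 1680 ± 477 CPM in C57BL/6, from 304 ± 96 to 2200 ± 252 CPM in C3H/HeJ and from 347 ± 143 to 1470 ± 585 CPM in KK/HlJ (SD, n = 2). Ltbp2, a microfibril-associated matrix protein, rose by 1.66 (SE 0.228; adjusted p = 0.00211). The 4 other calls were Sfrp2, a secreted modulator of Wnt signalling (1.51, SE 0.276, adjusted p = 0.0424), Serpina3n, a secreted protease inhibitor (1.29, SE 0.214, 0.0159), Cilp, a matrix protein first described in cartilage (1.22, SE 0.204, 0.0159), and the secreted protein Pamr1 (1.15, SE 0.188, 0.0159). In 6 of 6 ISO libraries Postn, Ltbp2, Sfrp2, Cilp and Pamr1 stood above both sham libraries of their strain, and Serpina3n did so in 5. The genes lie on mm10 at chromosome 3, 54361109 to 54391037 (Postn), chromosome 12, 84783212 to 84876532 (Ltbp2), chromosome 3, 83766321 to 83774316 (Sfrp2), chromosome 12, 104406729 to 104414329 (Serpina3n), chromosome 9, 65265180 to 65280605 (Cilp), and chromosome 2, 102550012 to 102643041 (Pamr1), each annotated as protein coding. The test called 6 genes higher and 0 lower, with 868 at an unadjusted p under 0.05. DESeq2 called 71, voom 5, the offsets 22 (20 higher, 2 lower) and a test without the filter on low counts 75 (55 higher, 20 lower). Postn and Ltbp2 kept their calls under each alternative and without each of the 12 libraries; a fit of only the groups compared kept 2 calls. Sfrp2 lost its call without any of the 4 C57BL/6 libraries, C3H/HeJ sham replicate 1, either C3H/HeJ ISO library or KK/HlJ ISO replicate 1 (adjusted p up to 0.309). Pamr1 lost it without either C57BL/6 sham library, C57BL/6 ISO replicate 2, C3H/HeJ sham replicate 1, C3H/HeJ ISO replicate 1 or KK/HlJ ISO replicate 1 (up to 0.112). Serpina3n lost it without C57BL/6 sham replicate 1, C57BL/6 ISO replicate 2, C3H/HeJ sham replicate 1 or C3H/HeJ ISO replicate 2 (up to 0.149), and Cilp without C57BL/6 sham replicate 1, C57BL/6 ISO replicate 1, C3H/HeJ sham replicate 1 or C3H/HeJ ISO replicate 1 (up to 0.132). Sfrp2 also lost it with voom and with a minimum of 5 CPM (adjusted p up to 0.213 over the alternatives). The count fell to 3 without C57BL/6 sham replicate 1, C3H/HeJ sham replicate 1 or C3H/HeJ ISO day 14 replicate 1, and rose to 60 without C3H/HeJ sham replicate 2, 23 without KK/HlJ sham replicate 1, 50 without KK/HlJ sham replicate 2, 234 without KK/HlJ ISO day 14 replicate 2 and 94 without the 4 divergent libraries. Of the 234 genes 28 were higher and 206 lower, against 82 and 12 of the 94, a count in which each KK/HlJ group and C3H/HeJ sham have 1 library.

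**Figure D1:**
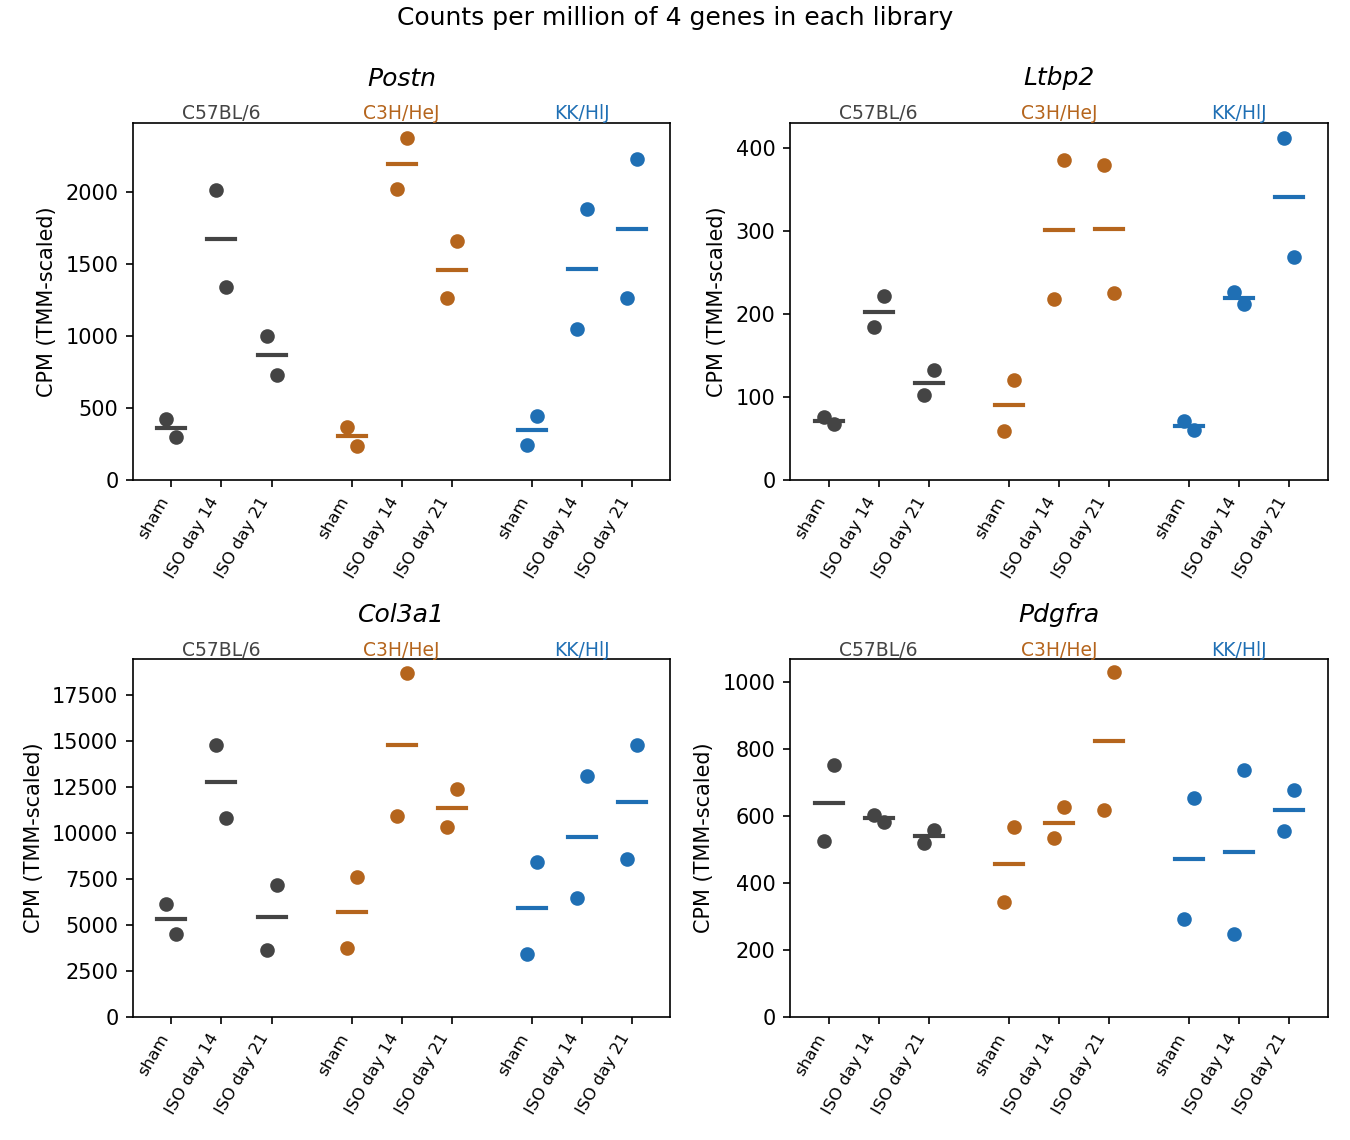
Normalised level (CPM) of Postn, Ltbp2, Col3a1 and Pdgfra in each of the 18 libraries, by strain and condition; points are libraries and bars are means of 2. In each strain both ISO libraries of each day lie above both sham libraries for Postn and Ltbp2, while Pdgfra overlaps between conditions except in C3H/HeJ at day 21 (617 and 1030 CPM, against 343 and 567 CPM in sham).

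The list of 35 activated fibroblast and matricellular genes, fixed in advance, rose at day 14, with a median log2 fold change of 1.11 (camera adjusted p = 4.98e-21, and 0.000475 with an estimated correlation). Over all genes 4 members rose, and 19 rose and 0 fell when adjusted over the list alone. They included Dkk3, a secreted Dickkopf family protein (1.11, SE 0.212), Ccn2, or connective tissue growth factor (1.39, SE 0.296), fibronectin (Fn1, 1.19), Comp (1.15) and tenascin-C (Tnc, 1.99). Of 31 collagen genes 0 rose over all genes and 4 adjusted over the list alone: Col3a1 (1.13), Col12a1 (1.39), Col14a1 (0.96) and Col5a2 (0.84). The collagen list was called with the preset correlation (median 0.39, adjusted p = 0.0026) and not with an estimated correlation (adjusted p = 0.563). Col1a1 differed by 0.51 (adjusted p = 0.783 over all genes). Acta2, smooth muscle actin, differed by 0.03, Pdgfra by 0.10 and Tcf21 by -0.02 (adjusted p = 1 for each). The sign of each turned with a setting: Acta2 was at -0.31 without the 4 divergent libraries, and Pdgfra at -0.18 and Tcf21 at 0.08 with the offsets for transcript length and GC content. Among 23 TGF-beta genes, Ccn2 alone rose adjusted over the list alone (median 0.42, camera adjusted p = 0.00202). Of 22 proteoglycans Prg4, or lubricin, rose adjusted over the list alone (1.40, with a list median of 0.34 and a camera adjusted p of 0.0131), and of 31 Wnt pathway genes Sfrp2, Dkk3 and Sfrp1 (0.72) did, all secreted modulators of the pathway (median 0.44, camera adjusted p = 0.0131). With an estimated correlation the adjusted p of these 3 lists was 0.374, 0.374 and 0.396. Without KK/HlJ ISO day 14 replicate 2 the collagen, proteoglycan and Wnt calls were lost (adjusted p up to 0.0568, 0.0936 and 0.091 over the libraries left out), as was the proteoglycan call without C3H/HeJ sham replicate 2 and the Wnt call without C57BL/6 ISO day 14 replicate 1. Of 28 resting fibroblast genes 0 changed over all genes, and Hsd11b1 (-1.15), Penk (-1.83) and Dpep1 (-0.58) fell adjusted over the list alone (median -0.01, camera adjusted p = 0.232).

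**Figure D2:**
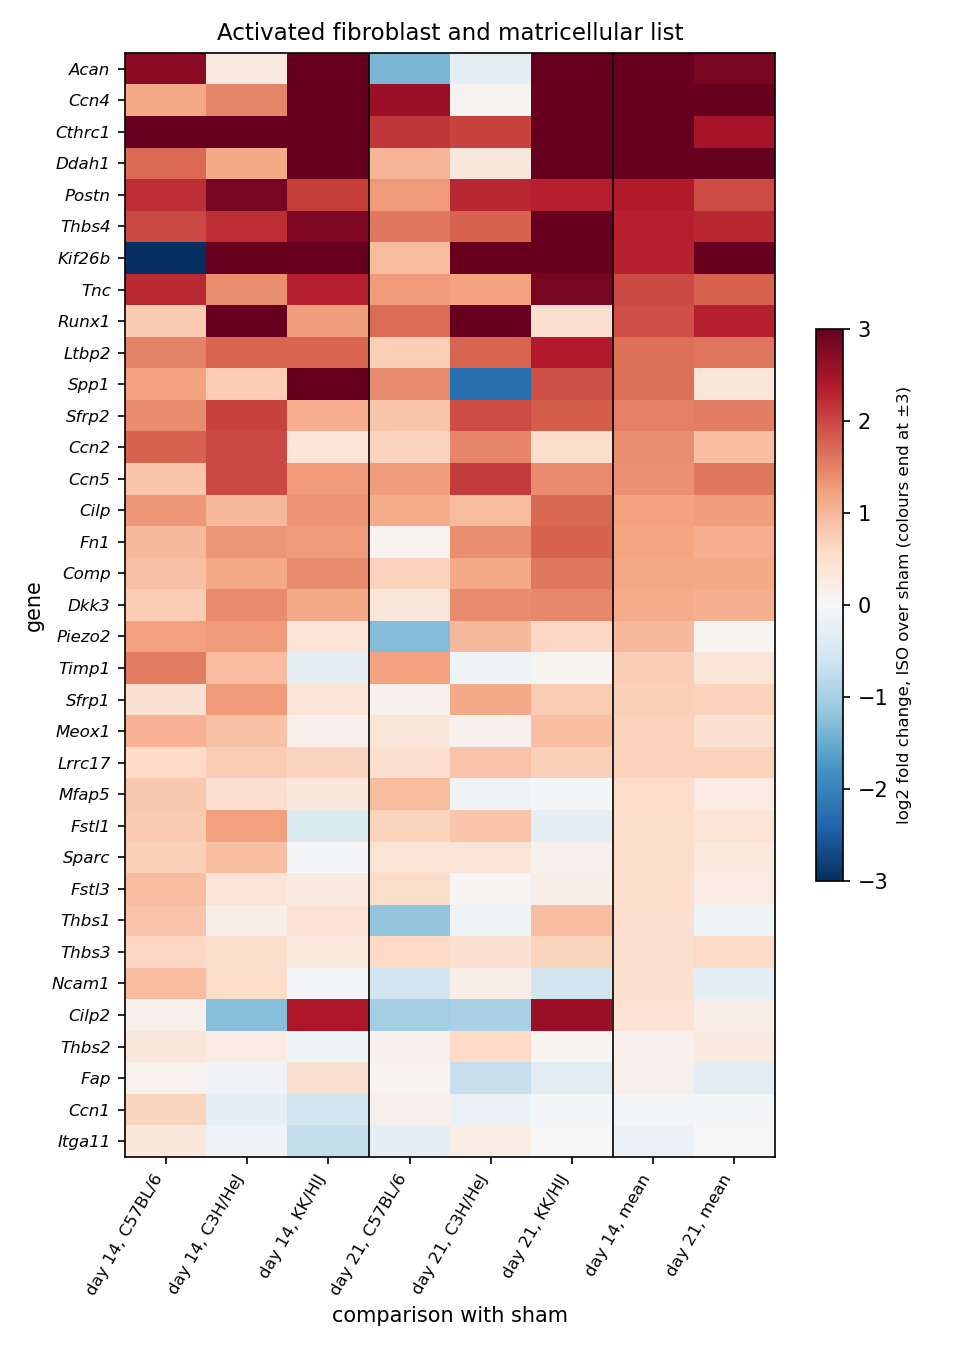
Heat map of log2 fold changes (ISO over sham, colour scale) of the 35 activated fibroblast and matricellular genes, one line per gene, over the 8 ISO comparisons in columns. Postn and Ltbp2 are above 0 in every column, and the median over the list was 1.11 at day 14 and 0.70 at day 21 for the means of 3 strains.

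Other lists moved at day 14 with the preset correlation only; beside each median stand the camera adjusted p with the preset and then with an estimated correlation. Oxidative phosphorylation genes had a median of -0.34 (adjusted p = 5.51e-07; 0.425 with an estimated correlation) and cytosolic ribosomal protein genes -0.32 (0.000376, then 0.425), with 0 members passing alone, and each median kept its sign under RLE scaling. With offsets for length and GC content the medians were -0.10 and -0.10. Complement genes had a median of 0.54 (0.013, then 0.374), metalloproteinases and inhibitors 0.30 (0.0185, then 0.425), Schwann and glia markers -0.42 (0.00321, then 0.374), and pericyte and smooth muscle markers -0.28 (0.00587, then 0.563), of which Vtn (-1.26) fell adjusted over the list alone. The pericyte call was lost without C57BL/6 sham replicate 1, C57BL/6 ISO replicate 1, C3H/HeJ sham replicate 2, KK/HlJ sham replicate 2 or KK/HlJ ISO replicate 2 (adjusted p up to 0.391) and the metalloproteinase call without C57BL/6 ISO replicate 1, C3H/HeJ sham replicate 2, KK/HlJ sham replicate 2 or KK/HlJ ISO replicate 1 (0.105). The complement call was lost without C57BL/6 ISO replicate 2 or C3H/HeJ sham replicate 2 (0.0946) and the ribosomal call without KK/HlJ sham replicate 1 (0.0596). Without the 4 divergent libraries the collagen, proteoglycan, metalloproteinase, complement and ribosomal calls were lost, with a minimum of 5 CPM those of proteoglycans, complement, mitosis and Schwann markers, and with the offsets the ribosomal call. Mitosis genes were near the floor, at a median of 1.75 CPM per member, so their fitted changes are no measure of size (adjusted p = 0.00113; 0.563). In lists not called as a whole, adjusted over the list alone, the alarmin Il33 (1.23), the chemokine Cx3cl1 (1.25), the glucose transporter Slc2a1 (1.07), the lysyl hydroxylase Plod2 (1.38) and the microfibril protein Mfap4 (0.90) rose, and the early-response genes Klf2 (-0.92) and Ier2 (-0.83) fell. The chaperone Hsph1 passed likewise (1.43), but differed by -0.21 in C57BL/6, against 3.22 in C3H/HeJ and 1.27 in KK/HlJ.

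At day 21, 6 genes rose and 1 fell in the mean over strains. Postn rose by 1.95 (SE 0.23; adjusted p = 0.00032), Ltbp2 by 1.61 (SE 0.228; 0.00325), Sfrp2 by 1.53 (SE 0.276; 0.0355), Cilp by 1.26 (SE 0.204; 0.0168) and Pamr1 by 1.06 (SE 0.188; 0.0355). Prg4 rose as well (1.43, SE 0.265; adjusted p = 0.0431; chromosome 1, 150449412 to 150466165, protein coding), and each of these 6 stood above both sham libraries in 6 of 6 ISO libraries. Gm13889, a predicted gene chosen after its values were seen, fell by 1.61 (adjusted p = 0.0355). Serpina3n differed by 0.84 (adjusted p = 0.377), Col3a1 by 0.67 (0.953) and Col1a1 by 0.25 (1). Acta2 differed by -0.65 (adjusted p = 0.953), from -0.97 in C57BL/6 and -0.86 in C3H/HeJ to -0.13 in KK/HlJ, and stood below both sham libraries in 5 of 6 ISO libraries. Pdgfra differed by 0.33 and Tcf21 by -0.16 (adjusted p = 1 for each). The test called 6 genes higher and 1 lower, with 803 at an unadjusted p under 0.05; DESeq2 called 41, voom 3, the offsets 11 and a test without the filter on low counts 55 (43 higher, 12 lower). Postn and Ltbp2 kept their calls under each alternative and without each of the 12 libraries, and a fit of only the groups compared kept 2 calls. Without C57BL/6 sham replicate 1, C57BL/6 ISO replicate 2, C3H/HeJ sham replicate 1 or C3H/HeJ ISO replicate 2, Sfrp2, Prg4, Cilp, Pamr1 and Gm13889 lost their calls (adjusted p up to 0.236, 0.279, 0.204, 0.25 and 0.307 over the libraries left out). All of these but Cilp also lost theirs without C3H/HeJ ISO replicate 1 or KK/HlJ ISO replicate 1. Sfrp2 and Prg4 lost theirs without either other C57BL/6 library, Pamr1 without C57BL/6 sham replicate 2 or KK/HlJ sham replicate 1, and Gm13889 without C57BL/6 ISO replicate 1 or KK/HlJ sham replicate 1. Voom ended the calls of Sfrp2, Prg4, Pamr1 and Gm13889, a minimum of 5 CPM those of Sfrp2, Prg4 and Gm13889, the offsets those of Prg4 and Gm13889, and the replicate block that of Prg4 (adjusted p up to 0.138 for Sfrp2, 0.143 for Prg4, 0.105 for Pamr1 and 0.433 for Gm13889 over the alternatives). The count was 2 without C57BL/6 sham replicate 1, 4 without C57BL/6 sham replicate 2 or ISO day 21 replicate 1, 3 without C57BL/6 ISO day 21 replicate 2, C3H/HeJ sham replicate 1, either C3H/HeJ ISO day 21 library or KK/HlJ ISO day 21 replicate 1, 52 without C3H/HeJ sham replicate 2, 12 and 34 without KK/HlJ sham replicates 1 and 2, 60 without KK/HlJ ISO day 21 replicate 2 (9 higher, 51 lower), and 78 without the 4 divergent libraries (69 higher, 9 lower).

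The activated fibroblast list rose again at day 21, with a median of 0.70 (adjusted p = 2.23e-15, and 0.00166 with an estimated correlation). Over all genes 4 members rose, and 16 rose and 0 fell adjusted over the list alone. Of 31 Wnt pathway genes 1 rose over all genes and 6 adjusted over the list alone, namely Sfrp2, Dkk3 (1.07), Frzb (0.96), Sfrp4 (1.77), Sfrp1 (0.68) and Nkd2 (0.81), which are modulators or inhibitors of Wnt signalling (median 0.31, adjusted p = 0.00573; 0.408 with an estimated correlation). Schwann and glia markers fell, with a median of -0.88 (adjusted p = 3.16e-06, and 0.0456 with an estimated correlation). Pericyte and smooth muscle markers had a median of -0.57 (adjusted p = 3.38e-06, and 0.498 with an estimated correlation), from -1.5 in C57BL/6 to -0.50 in C3H/HeJ (adjusted p = 0.188) and 0.03 in KK/HlJ (0.788), so that C57BL/6 alone passed within strains. That C57BL/6 call held with the preset correlation only. Vtn (-1.23) and Des (-0.99) fell adjusted over the list alone. Collagens were not called (median 0.27, adjusted p = 0.0858), although Col12a1 (1.53) and Col14a1 (0.80) rose adjusted over the list alone. Oxidative phosphorylation and ribosomal protein genes had medians of -0.30 and -0.31 (adjusted p = 2.83e-06 and 0.000358, and 0.498 for each with an estimated correlation), and -0.11 and -0.12 with the offsets. In C57BL/6 both were higher (0.34 and 0.56), against -0.79 and -0.66 in C3H/HeJ and -0.55 and -0.78 in KK/HlJ. Complement (median 0.50), TGF-beta (0.30), interferon-stimulated (-0.29) and endothelial (0.61) lists were called with the preset correlation (adjusted p = 0.00663, 0.0407, 0.0138 and 0.00889) and not with an estimated correlation (adjusted p = 0.384, 0.533, 0.498 and 0.623). The endothelial median was -1.07 in C57BL/6, 2.34 in C3H/HeJ and 1.33 in KK/HlJ, and its call was lost without C3H/HeJ ISO day 21 replicate 1, the library with the most endothelial reads (adjusted p = 0.683), and without KK/HlJ sham replicate 1 (0.0616). The interferon call was lost without C57BL/6 sham replicate 1, C3H/HeJ sham replicate 1, KK/HlJ sham replicate 2 or KK/HlJ ISO replicate 2 (up to 0.375), and the TGF-beta call without C57BL/6 sham replicate 2, C57BL/6 ISO replicate 1, C3H/HeJ sham replicate 1, C3H/HeJ ISO replicate 2 or any KK/HlJ library (0.236). Without KK/HlJ ISO replicate 2 the complement, mitosis and ribosomal calls were lost (up to 0.0513, 0.0933 and 0.124), the last also without KK/HlJ sham replicate 1. Without the 4 divergent libraries the TGF-beta, complement, ribosomal, Wnt, macrophage and endothelial calls were lost, with the offsets those of TGF-beta and ribosomal genes, and with a minimum of 5 CPM that of mitosis genes. Macrophage and monocyte markers (adjusted p = 0.00573; 0.498 with an estimated correlation) and mitosis genes (0.000255, then 0.575) were near the floor, and the macrophage call was lost without C3H/HeJ ISO replicate 1 or KK/HlJ sham replicate 2 (up to 0.321). Il33 rose adjusted over the list alone. Hsph1 passed likewise (1.29), but differed by -0.30 in C57BL/6, against 2.48 in C3H/HeJ and 1.70 in KK/HlJ.

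In C57BL/6 Postn and Ltbp2 stood higher with ISO without passing the test over all genes. At day 14 Postn differed by 2.22 (adjusted p = 0.234) and Ltbp2 by 1.5 (adjusted p = 1), from 71.7 ± 5.5 to 202 ± 25.7 CPM (SD, n = 2). Of the 35 activated fibroblast genes 0 rose over all genes and 5 adjusted over the list alone, Postn, Ltbp2, Cilp (1.31), Ccn2 (1.77) and Sfrp2 (1.42). The list median was 0.92 (camera adjusted p = 6.89e-18, and 0.000912 with an estimated correlation). At day 21 Postn differed by 1.27 and Ltbp2 by 0.72 (adjusted p = 1 for each), 0 members passed, and the list median of 0.67 was called with the preset correlation (8.41e-05) and not with an estimated correlation (adjusted p = 0.147). Col1a1 differed by 0.63 at day 14 and 0.10 at day 21, and Col3a1 by 1.27 and 0.03 (adjusted p = 1 for each). Both day 21 values turned negative with voom, without C57BL/6 sham replicate 2 and without ISO day 21 replicate 2 (-0.54 for Col1a1 and -0.53 for Col3a1 in the last). At day 21 8 of 20 pericyte and smooth muscle markers fell adjusted over the list alone and 0 over all genes, among them the receptor Pdgfrb (-1.46), Rgs4 (-2.25), Cspg4 (-1.78) and Mylk (-2.03). Their median was -1.5 (adjusted p = 1.22e-11; 0.345 with an estimated correlation), and their summed level was 8937 and 5259 CPM in sham and 3673 and 1771 CPM at day 21. edgeR called 0 genes at day 14 (173 at an unadjusted p under 0.05; DESeq2 7, voom 1) and 0 at day 21 (326; DESeq2 7, voom 0). Leaving out each library in turn brought no calls with the same genes held. Some of these fits did bring calls with the filter derived again, at both days. Each of them leaves a group with 1 library.

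In C3H/HeJ, Postn rose by 2.85 (SE 0.412; edgeR adjusted p = 0.00915) and Serpina3n by 2.35 (SE 0.384; 0.0279) at day 14. Serpina3n went from 76.1 and 110 CPM in the sham libraries to 345 and 607 CPM. Ltbp2 differed by 1.75 at each day (adjusted p = 0.435 and 0.603), from 89.9 ± 43.9 CPM in sham to 302 ± 118 CPM at day 14 and 302 ± 109 CPM at day 21 (SD, n = 2). Of the activated fibroblast genes 1 rose over all genes and 11 adjusted over the list alone at day 14 (median 1.13; adjusted p = 1.37e-08, and 0.0144 with an estimated correlation), and 0 and 8 at day 21 (median 0.83; 7.11e-05, and 0.121 with an estimated correlation). Hsph1 rose adjusted over the list alone at both days (3.22 and 2.48). So did Il33 (2.14 and 1.72) and the metalloproteinase inhibitor Timp3 (1.54 and 1.65). The rise of Hsph1 rests on low C3H/HeJ sham libraries (9.27 and 14.4 CPM), which also gave its sham difference from C57BL/6. At day 21 Postn differed by 2.26 (adjusted p = 0.186). Oxidative phosphorylation genes had medians of -0.49 and -0.79 at the 2 days (adjusted p = 6.15e-07 and 6.34e-11; 0.58 and 0.385 with an estimated correlation). edgeR called 2 genes higher and 0 lower at day 14 (484 at an unadjusted p under 0.05; DESeq2 17, voom 1) and 0 at day 21 (911; DESeq2 15, voom 0). A fit of only the groups compared and a minimum of 5 CPM each ended both day 14 calls, the offsets that of Postn, and voom and leaving out the 4 divergent libraries that of Serpina3n (adjusted p up to 0.965 for each). Both calls were also lost without C3H/HeJ sham replicate 1 or ISO day 14 replicate 2, in fits with the same genes held. These fits leave a group with 1 library. More genes were called in each of them with the filter derived again than with the genes held. Leaving out C3H/HeJ sham replicate 2 raised the counts at both days in either version.

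In KK/HlJ, Ltbp2 rose by 2.38 (SE 0.405) and Postn by 2.33 (SE 0.404) at day 21, each with an edgeR adjusted p of 0.0471. Ltbp2 went from 65.7 ± 7.83 CPM in sham to 219 ± 9.92 CPM at day 14 and 341 ± 101 CPM at day 21 (SD, n = 2). Uggt2, a glucosyltransferase of the endoplasmic reticulum, was the other call (edgeR adjusted p = 0.0471, chromosome 14, 118985039 to 119099430, protein coding). It had 1 count in each sham library (0.0871 and 0.0924 CPM) and stood at 17.7 and 25.1 CPM at day 21. In C57BL/6 and C3H/HeJ it stood at 4.4 to 15.4 CPM in sham and 4.99 to 28.7 CPM with ISO. Only the KK/HlJ sham libraries were thus low. The same libraries gave its sham call against C3H/HeJ (-6.67), so the 2 calls are not separate results. At day 14 Postn differed by 2.08 (adjusted p = 0.249) and Ltbp2 by 1.74 (0.417). Of the activated fibroblast genes 0 rose over all genes and 10 adjusted over the list alone at day 14 (median 1.10; adjusted p = 7.44e-07, and 0.0311 with an estimated correlation), and 2 and 10 at day 21 (median 0.94; 9.76e-10, and 0.00926 with an estimated correlation). Among the latter were Cilp (1.72), Dkk3 (1.44), Fn1 (1.77) and Comp (1.58). Ribosomal protein genes had medians of -0.45 (0.0045; 0.722 with an estimated correlation) and -0.78 (5.96e-07, and 0.682 with an estimated correlation), calls lost without KK/HlJ sham replicate 1 or ISO replicate 2 (up to 0.792 at day 14 and 0.118 at day 21). edgeR called 0 genes at day 14 (747 at an unadjusted p under 0.05; DESeq2 87, voom 0) and 3 higher and 0 lower at day 21 (824; DESeq2 65, voom 0). The 3 genes lost their calls without KK/HlJ sham replicate 1 or ISO day 21 replicate 1 (adjusted p up to 0.511 for Ltbp2, 0.27 for Postn and 0.21 for Uggt2), under RLE scaling, with the replicate block, with voom and with a minimum of 5 CPM (up to 1 over the alternatives), Uggt2 also in a fit of only the groups compared and Postn with the offsets; counts at day 21 were 8 and 112 without sham replicates 1 and 2, 0 and 148 without ISO replicates 1 and 2, and at day 14 12 and 56, and 1 and 477, in the same order. Of the 148 genes 10 were higher and 138 lower, and of the 477 genes 36 were higher and 441 lower.

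Between day 14 and day 21, Postn differed by -0.95 in C57BL/6 (adjusted p = 0.903), -0.59 in C3H/HeJ and 0.25 in KK/HlJ. Ltbp2 differed by -0.78 (0.903), 0.00 and 0.64. None of these passed the test, and Postn in KK/HlJ was at -0.11 without ISO day 14 replicate 1 and at -0.21 without ISO day 21 replicate 2. edgeR called 0 genes in C57BL/6 (542 at an unadjusted p under 0.05; DESeq2 13, voom 0), 0 in C3H/HeJ (66; 0 and 0) and 0 in KK/HlJ (166; 2 and 0). A fit of only the groups compared called 55 in C57BL/6. Without KK/HlJ ISO day 14 replicate 2 there were 425 calls in KK/HlJ, without KK/HlJ ISO day 21 replicate 2 there were 157, and without C3H/HeJ ISO day 21 replicate 2 there was 1 in C3H/HeJ.

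Whether strains differ in their response was tested as a difference of differences. The response of Postn at day 21 was larger in C3H/HeJ than in C57BL/6 by 0.99 (SE 0.545; adjusted p = 0.801) and in KK/HlJ than in C57BL/6 by 1.07 (0.763). That of Ltbp2 was larger by 1.03 (0.801) and by 1.66 (SE 0.549; 0.703). None of these passed the test. At day 14 Postn differed by 0.63, -0.14 and -0.77 and Ltbp2 by 0.25, 0.24 and -0.01 for C3H/HeJ against C57BL/6, KK/HlJ against C57BL/6 and KK/HlJ against C3H/HeJ (adjusted p = 1 for each). The day 14 response of Serpina3n, chosen after its values were seen, was lower in KK/HlJ than in C3H/HeJ by a difference of -1.81 (adjusted p = 1). In that order of pairs edgeR called 0, 0 and 0 genes at day 14 (270, 586 and 524 at an unadjusted p under 0.05; DESeq2 2, 25 and 2; voom 0 in each) and 0, 0 and 0 at day 21 (972, 1017 and 534; DESeq2 1, 15 and 6; voom 0 in each). Without C3H/HeJ sham replicate 2 the count against C57BL/6 was 47 at day 14 and 167 at day 21, and that of KK/HlJ against C3H/HeJ 32 and 34. For KK/HlJ against C57BL/6 the counts were 7 and 6 without KK/HlJ sham replicate 1, 15 and 88 without sham replicate 2, 282 and 108 without ISO replicate 2, and 1 at day 14 without ISO replicate 1; against C3H/HeJ they were 7 and 7, 14 and 8, 360 and 125, and 1.

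At each day 1 strain alone had ISO calls, C3H/HeJ with 2 at day 14 and KK/HlJ with 3 at day 21, so the strains' calls could not overlap. Across the 8709 genes with a mean of at least 10 CPM, the fold changes of 2 strains correlated at r = 0.263 (C3H/HeJ and C57BL/6), 0.016 (KK/HlJ and C57BL/6) and 0.151 (KK/HlJ and C3H/HeJ) at day 14, and at -0.229, -0.249 and 0.34 at day 21; genes are not independent replicates. The fold changes also ran with transcript length across these genes, with rho of 0.08, 0.38 and 0.22 in C57BL/6, C3H/HeJ and KK/HlJ at day 14 and -0.32, 0.51 and 0.32 at day 21.

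In sham libraries 31 genes were called over the 3 pairs of strains, of which 10 share at least 50% of their 25-base words with another gene and are uncertain. Gbp2b, a guanylate-binding protein, had 0 counts in both C57BL/6 sham libraries and was at least 123-fold higher in C3H/HeJ and at least 292-fold higher in KK/HlJ (floor of 3 counts per library; chromosome 3, 142594847 to 142619179). The chaperones Hspa8 (-3.02, SE 0.446, edgeR adjusted p = 0.0016) and Hsph1 (-3.32, SE 0.568, 0.0108) were lower in C3H/HeJ than in C57BL/6. So was the cyclin Ccnd1 (-2.95, SE 0.572, 0.0478), while Hddc3 was higher (2.99, SE 0.521, 0.0108). Hspa8 stood at 42.3 to 62.8 CPM in every C3H/HeJ library and at 163 to 496 CPM in the others. It is uncertain, since reads lowered or moved by strain variants were not tested for it. Hsph1 stood at 9.27 and 14.4 CPM in C3H/HeJ sham, 55.9 to 126 CPM with ISO there, and 30.2 to 162 CPM in C57BL/6. Its sham difference and its ISO rise in C3H/HeJ thus rest on the same sham libraries. KK/HlJ had more Wfdc2, a secreted protein with whey acidic protein domains (5.89 over C57BL/6, SE 0.877; 0.00227), and less of the prohormone-processing enzyme Cpe (-2.76, SE 0.414; 0.00227). Against C3H/HeJ, KK/HlJ was higher in the Notch coactivator Maml2 (3.35, SE 0.673, edgeR adjusted p = 0.0401) and lower in Gimap6 (-2.55, SE 0.515, 0.0414). It was also higher in Serpina3n (1.96, SE 0.379, 0.0316), chosen after its values were seen. Tnxa, annotated as a pseudogene, stood at 58.5 and 47.9 CPM in C3H/HeJ sham libraries and at most 0.0924 CPM in the sham libraries of the other strains. C1rb, at 41.5 and 25.8 CPM in C3H/HeJ sham, is uncertain, since it shares 75.4% of its words with C1ra. Its log2 ratio to C57BL/6 was 5.84 but that of both genes together 0.46, and for KK/HlJ against C3H/HeJ these were -5.97 and 0.28. Ribosomal genes with near-identical copies are uncertain: Rps3a1 stood at 0.0786 and 0.857 CPM in C3H/HeJ sham against 70.9 to 119 CPM in the others, while its copy Rps3a3 stood at 396 and 217 CPM in C3H/HeJ. Rpl26 and Rps18, which share fewer words with other genes than the 50% set as the threshold, were also near the floor in C3H/HeJ sham. Rpl26 is uncertain, since reads lowered or moved by strain variants were not tested for it. Rps18 is uncertain too, being the closest copy of Gm10260, which stood at 241 and 142 CPM in C3H/HeJ sham and at most 0.348 CPM in the other sham libraries. edgeR called 9 genes higher and 7 lower in C3H/HeJ against C57BL/6 (DESeq2 82, voom 59), 7 and 1 in KK/HlJ against C57BL/6 (77 and 11), and 17 and 7 in KK/HlJ against C3H/HeJ (161 and 3). Strain cannot be told apart from any batch that followed strain.

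Most of these sham calls were lost without at least 1 of the libraries compared. The losses listed here are those of genes named above, and those of C4b are given further below. Gbp2b, Rps3a1 and Rps3a3 kept their calls without each library in turn, as did Hspa8 for C3H/HeJ against C57BL/6. Hspa8 was also called for KK/HlJ against C3H/HeJ (2.45, adjusted p = 0.0155; chosen after its values were seen), and lost that call without either C3H/HeJ sham library or KK/HlJ sham replicate 1 (up to 0.195). Without C57BL/6 sham replicate 1, Tnxa, C1rb, Hddc3, Hsph1 and Ccnd1 lost theirs against C3H/HeJ and Wfdc2 and Cpe against KK/HlJ; without replicate 2, C1rb, Hddc3 and Wfdc2 did. Without C3H/HeJ sham replicate 1, C1rb, Hddc3, Rpl26, Hsph1 and Ccnd1 lost theirs against C57BL/6, and Rps18, Rpl26, Wfdc2, Maml2, C1rb, Uggt2, Gimap6 and Serpina3n against KK/HlJ; without replicate 2, Rps18 did. Without KK/HlJ sham replicate 1, Wfdc2 lost both its calls, and Rps18, Maml2, C1rb, Tnxa, Uggt2 and Gimap6 lost theirs against C3H/HeJ. Without KK/HlJ sham replicate 2, C1rb, Uggt2, Gimap6 and Serpina3n lost theirs against C3H/HeJ. A fit of only the groups compared ended the calls of Gbp2b, Hddc3, Rps3a1, Ccnd1, Wfdc2 and Cpe against C57BL/6 and of Maml2, Gimap6, Uggt2 and Serpina3n against C3H/HeJ, and voom those of Hsph1, Rpl26, Wfdc2 and Cpe and of each gene named for KK/HlJ against C3H/HeJ. The highest adjusted p without a library was 0.874 for C1rb, 0.736 for Ccnd1, 0.617 for Hddc3 and 0.533 for Wfdc2. The count for C3H/HeJ against C57BL/6 was 8 without C57BL/6 or C3H/HeJ sham replicate 1 and 151 without C3H/HeJ sham replicate 2. That for KK/HlJ against C57BL/6 was 3 without C57BL/6 sham replicate 1, 20 without KK/HlJ sham replicate 1 and 64 without replicate 2, and that for KK/HlJ against C3H/HeJ was 6 and 119 without C3H/HeJ sham replicates 1 and 2 and 100 without KK/HlJ sham replicate 2.

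**Figure D3:**
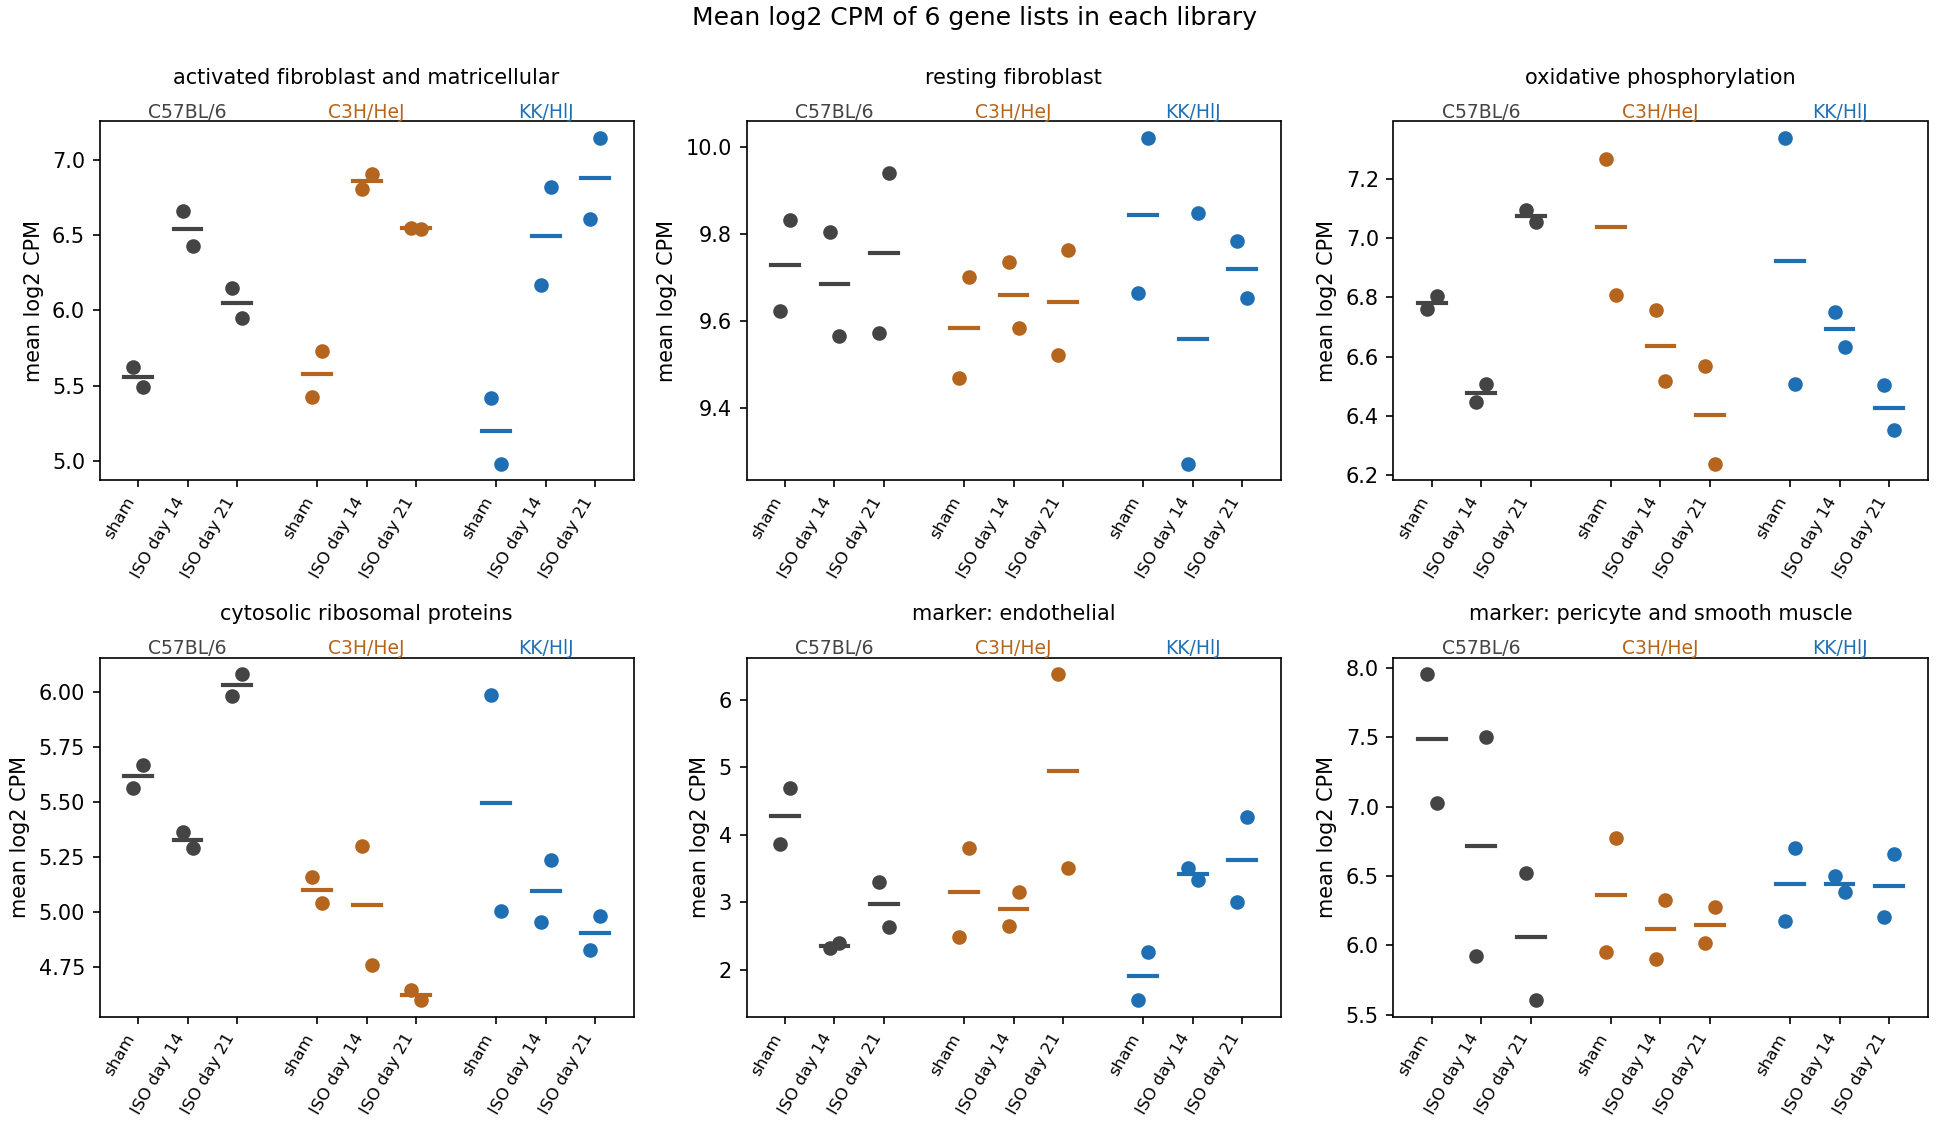
Mean log2 CPM of 6 gene lists in each of the 18 libraries, by strain and condition; each point is a library. The activated fibroblast list lies higher in both ISO libraries than in both sham libraries in each strain and day, and the endothelial markers reach 6.38 in C3H/HeJ ISO day 21 replicate 1.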

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

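The 34 lists tested and the 8 genes reported throughout were examined. The tests of the 4 divergent libraries and of transcript length and GC content were chosen after the data were seen.

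For 21 of 204 list differences between strains, camera with the preset correlation found the ISO response to differ, and with an estimated correlation it did so for 0. Values are median differences in log2 fold change. At day 14 the response was larger in C3H/HeJ than in C57BL/6 for heat shock (0.65), endoplasmic reticulum stress (0.67) and cardiomyocyte marker genes (1.15), and lower for oxidative phosphorylation (-0.2). In KK/HlJ it was lower than in C57BL/6 for collagens (-0.41) and higher for endothelial markers (2.57). Against C3H/HeJ it was lower for endoplasmic reticulum stress (-0.75) and higher for endothelial markers (1.61). Macrophage markers differed from C57BL/6 by 5.81 in C3H/HeJ and 4.81 in KK/HlJ, fitted values of genes near the floor that are no measure of size. At day 21 the response of activated fibroblast genes was larger in KK/HlJ than in C57BL/6 (0.62). C3H/HeJ and KK/HlJ differed from C57BL/6 in oxidative phosphorylation (-1.14 and -0.89), ribosomal protein (-1.15 and -1.4), endothelial (2.88 and 2.55) and pericyte and smooth muscle genes (0.86 and 1.68), and C3H/HeJ also in immediate-early genes (0.85). Cardiomyocyte markers were lower in KK/HlJ than in C3H/HeJ (-1.4).

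Of these 21 differences 15 were lost without at least 1 library. At day 21 the endothelial difference of C3H/HeJ from C57BL/6 was 1.04 without C3H/HeJ ISO replicate 1 (adjusted p = 0.236), where the median in C3H/HeJ itself went from 2.34 to -0.29, and that of KK/HlJ was 1.0 without KK/HlJ ISO replicate 2, still called. The cardiomyocyte difference was -0.41 without C3H/HeJ ISO replicate 1 (0.562) and was also lost without KK/HlJ sham replicate 2. The pericyte calls were lost without C57BL/6 sham replicate 1 or ISO replicate 2 (up to 0.364 and 0.0914), that of C3H/HeJ also without C3H/HeJ sham replicate 1, the immediate-early call without C57BL/6 ISO replicate 1 (0.0692), and the activated fibroblast call without C57BL/6 sham replicate 1, C57BL/6 ISO replicate 2, KK/HlJ sham replicate 2 or either KK/HlJ ISO library (0.424). At day 14 the heat shock call and the endoplasmic reticulum stress call against C57BL/6 were lost without C57BL/6 sham replicate 1, C57BL/6 ISO replicate 2, C3H/HeJ sham replicate 2 or C3H/HeJ ISO replicate 1 (0.596 and 0.343), and the oxidative phosphorylation call without C57BL/6 sham replicate 1, C57BL/6 ISO replicate 2, C3H/HeJ sham replicate 1 or C3H/HeJ ISO replicate 2 (0.729). The cardiomyocyte call was lost without C57BL/6 sham replicate 1 or C3H/HeJ sham replicate 2 (0.079) and the collagen call without C57BL/6 sham replicate 2, C57BL/6 ISO replicate 1, KK/HlJ sham replicate 2 or KK/HlJ ISO replicate 1 (0.336). Of KK/HlJ against C3H/HeJ, the stress call was lost without C3H/HeJ sham replicate 2, C3H/HeJ ISO replicate 1, KK/HlJ sham replicate 1 or KK/HlJ ISO replicate 2 (0.326) and the endothelial call without C3H/HeJ sham replicate 2 or KK/HlJ sham replicate 1 (0.107). The macrophage calls were lost without C3H/HeJ sham replicate 2 (0.059) and, for KK/HlJ, without C57BL/6 sham replicate 2, C57BL/6 ISO replicate 2, KK/HlJ sham replicate 2 or KK/HlJ ISO replicate 1 (0.247).

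In 14 of 68 sets of a list and a day, both ISO libraries of one strain lay above both of its sham libraries while both of another strain lay below. Chance gives this in 13.9% of sets, and the lists are not independent of each other. These opposite directions were not tested as such, although camera called the differences above for some of the same lists. Values are ISO minus sham in mean log2 CPM. At day 14 DNA replication genes differed by -0.18, 0.32 and 0.58 in C57BL/6, C3H/HeJ and KK/HlJ, lipid uptake and adipogenesis genes by -0.38, -0.44 and 0.68, and macrophage markers by -0.91, 1.64 and 1.3. In C57BL/6 and KK/HlJ, MHC class II and dendritic markers differed by -0.37 and 1.25, endothelial markers by -1.91 and 1.51, and lymphatic endothelial markers by -0.58 and 1.43, while mast cell markers differed by 0.41 in C3H/HeJ and -1.59 in KK/HlJ. Macrophage, mast cell and lymphatic endothelial markers were near the floor, at medians of 1.66, 0.811 and 0.944 CPM per member, so their differences here and at day 21 are no measure of size, and the mast cell markers summed to 0 CPM in KK/HlJ ISO day 14 replicate 1, the library with the lowest total. At day 21 oxidative phosphorylation genes differed by 0.29, -0.63 and -0.49 in the 3 strains and ribosomal protein genes by 0.42, -0.48 and -0.59. DNA replication genes differed by 0.21 in C57BL/6 and -0.25 in C3H/HeJ, immediate-early genes by -0.63 and 0.31, and lymphatic endothelial markers by -0.95 and 1.79. In C57BL/6 and KK/HlJ lipid genes differed by -0.3 and 0.42 and endothelial markers by -1.3 and 1.73.

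Oxidative phosphorylation and ribosomal protein genes moved apart between strains, with medians that spanned 1.14 and 1.34 over the 6 comparisons of ISO with sham within strains. With offsets for transcript length and GC content the spans were 0.45 and 0.64, which is consistent with trends along length or GC content between libraries as a source of part of the pattern. Without the 4 divergent libraries they were 0.85 and 0.97, which argues against those libraries as the whole cause. A difference between the strains stays open and was not separated from these trends.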

How the results depend on the processing

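Postn and Ltbp2 in the means over strains kept their direction and their calls at both days under each alternative run and without each library, with adjusted p up to 0.0028 and 0.00971 for Postn and 0.0244 and 0.0286 for Ltbp2 over the alternatives at days 14 and 21. Other calls depended on the processing, and except where fewer genes or fewer libraries were fitted the cause was not tested. Leaving out 1 library leaves a group with 1, which is assumed to vary like the other groups. Leaving out the 4 divergent libraries does so for C3H/HeJ sham and each KK/HlJ group, so the KK/HlJ counts then compare 1 library with 1, and so does the KK/HlJ part of the means. Depth limits genes near the floor, such as Mki67, whose fitted fold changes are no measure of size. Detection also differed at a matched depth of 7230741 counts, with 11661 genes in KK/HlJ ISO day 21 replicate 1 and 18821 in replicate 2. Of 8712 genes with a mean of at least 10 CPM, 262 had 0 counts in KK/HlJ ISO day 14 replicate 1 and 133 in ISO day 21 replicate 1. These libraries stood alone in their groups where replicate 2 was left out and most calls were lower. Whether the zeros produced those calls was not tested. DESeq2 calls hold more false calls in the simulated data. The settings chosen after the data were seen are voom, the minimum of 5 CPM, the offsets and leaving out the 4 divergent libraries. Holding the 15762 genes in fits with fewer libraries was chosen after the counts with the filter derived again were seen.

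Counts of called genes are given in this order: ISO against sham at days 14 and 21 in C57BL/6, C3H/HeJ, KK/HlJ and their mean (both days in turn), day 21 against day 14 in the strains, sham C3H/HeJ against C57BL/6, KK/HlJ against C57BL/6 and KK/HlJ against C3H/HeJ, and these pairs for the response at day 14 and at day 21. The edgeR test called 0, 0, 2, 0, 0, 3, 6, 7, 0, 0, 0, 16, 8, 24, 0, 0, 0, 0, 0 and 0 genes.

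DESeq2 called 7, 7, 17, 15, 87, 65, 71, 41, 13, 0, 2, 82, 77, 161, 2, 25, 2, 1, 15 and 6. RLE scaling gave 0, 0, 2, 0, 0, 0, 7, 7, 0, 0, 0, 16, 10, 31, 0, 0, 0, 0, 0 and 0. Without a filter on low counts the counts were 4, 21, 23, 26, 41, 41, 75, 55, 19, 8, 5, 59, 59, 103, 2, 19, 9, 32, 38 and 3. Fits of only the groups compared gave 0, 1, 0, 17, 10, 8, 2, 2, 55, 0, 1, 17, 0, 35, 0, 0, 0, 0, 0 and 2. The same with the filter derived again gave 0, 0, 0, 0, 0, 0, 2, 2, 0, 0, 0, 0, 0, 4, 0, 0, 0, 0, 0 and 1. Voom called 1, 0, 1, 0, 0, 0, 5, 3, 0, 0, 0, 59, 11, 3, 0, 0, 0, 0, 0 and 0. A minimum of 5 CPM gave 0, 0, 0, 0, 0, 0, 5, 4, 0, 0, 0, 13, 8, 17, 0, 0, 0, 0, 0 and 0. The offsets gave 0, 0, 1, 0, 0, 2, 22, 11, 0, 0, 0, 25, 14, 28, 0, 0, 0, 0, 0 and 0. Leaving out the 4 divergent libraries gave 1, 1, 3, 1, 61, 56, 94, 78, 5, 0, 1, 40, 96, 69, 0, 20, 11, 0, 22 and 12. With the filter derived again as well it gave 27, 137, 385, 227, 186, 221, 595, 560, 169, 31, 7, 484, 315, 427, 97, 114, 75, 41, 186 and 81.

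Without each library in turn, in the same order, the lowest and highest counts were 0 to 0, 0 to 0, 0 to 111, 0 to 182, 1 to 477, 0 to 148, 3 to 234, 2 to 60, 0 to 0, 0 to 1, 0 to 425, 8 to 151, 3 to 64, 6 to 119, 0 to 47, 0 to 282, 0 to 360, 0 to 167, 0 to 108 and 0 to 125. These fits held the 15762 genes. With the filter derived again, as these fits were first run, the highest count was larger in every comparison and the lowest was as large or larger. The low counts without a library thus depend on holding the genes, a choice made after the counts were seen.

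The replicate number as a block gave 0, 0, 2, 0, 0, 0, 8, 6, 0, 0, 0, 15, 9, 20, 0, 0, 0, 0, 0 and 0 calls. Over 36 pairs of groups, the deviations of same-numbered libraries correlated above 0.1 in 15 and below -0.1 in 14, from -0.423 to 0.44. The signs followed 2 sets of groups, drawn up from these correlations. C57BL/6 sham, C3H/HeJ ISO day 21 and KK/HlJ ISO at both days stood against all other groups. Every correlation below -0.1 lay between the sets. Those above 0.1 lay within a set, except KK/HlJ sham with ISO day 14 (0.119). The replicate number thus does not pair the samples as it stands. A block with the numbers reversed between the sets was not fitted. With the block, Col3a1 at day 21 in C57BL/6 was -0.12, of the opposite sign. Mki67 at day 14 in KK/HlJ, with 0 counts in all 4 libraries, was fitted at 0 and has no sign; the block gave -0.29, voom -0.009 and no filter 0.

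Values that changed sign, in log2 fold change or as list medians, were these. With voom these were Acta2 (day 14 C57BL/6) -0.094, Col1a1 (day 21 C57BL/6) -0.006, Col3a1 (day 21 C57BL/6) -0.05, Pdgfra (day 14 KK/HlJ) -0.19, Acta2 (day 14 mean) -0.067 and Ltbp2 (day 21 against day 14 C3H/HeJ) -0.06. With only the groups compared these were Col3a1 (day 21 C57BL/6) -0.008. With only the groups compared and the filter derived again these were Col3a1 (day 21 C57BL/6) -0.004. With the offsets these were Pdgfra (day 21 C57BL/6) 0.11, Pdgfra (day 14 C3H/HeJ) -0.35, Pdgfra (day 21 C3H/HeJ) -0.038, Tcf21 (day 21 C3H/HeJ) 0.024, Pdgfra (day 14 KK/HlJ) -0.076, Tcf21 (day 14 KK/HlJ) 0.20, Pdgfra (day 14 mean) -0.18, Tcf21 (day 14 mean) 0.084, Ltbp2 (day 14 response C3H/HeJ against C57BL/6) -0.077, Ltbp2 (day 14 response KK/HlJ against C57BL/6) -0.012, Ltbp2 (day 14 response KK/HlJ against C3H/HeJ) 0.064, Ltbp2 (day 21 against day 14 C3H/HeJ) -0.16 and oxidative phosphorylation (day 21 against day 14 C3H/HeJ) -0.013. With the 4 divergent libraries left out these were Col1a1 (day 21 C3H/HeJ) -0.084, Acta2 (day 14 KK/HlJ) -0.43, Acta2 (day 14 mean) -0.31, Ltbp2 (day 14 response C3H/HeJ against C57BL/6) -0.17, Ltbp2 (day 14 response KK/HlJ against C3H/HeJ) 0.47, Postn (day 21 response KK/HlJ against C3H/HeJ) -0.32, oxidative phosphorylation (sham KK/HlJ against C57BL/6) -0.19 and cytosolic ribosomal proteins (sham KK/HlJ against C57BL/6) -0.15. With these left out and the filter derived again these were Col1a1 (day 21 C3H/HeJ) -0.084, Acta2 (day 14 KK/HlJ) -0.42, Acta2 (day 14 mean) -0.31, Ltbp2 (day 14 response C3H/HeJ against C57BL/6) -0.17, Ltbp2 (day 14 response KK/HlJ against C3H/HeJ) 0.47 and Postn (day 21 response KK/HlJ against C3H/HeJ) -0.32. With RLE scaling these were Ltbp2 (day 21 against day 14 C3H/HeJ) -0.003. With DESeq2 these were Ltbp2 (day 21 against day 14 C3H/HeJ) -0.003. With a minimum of 5 CPM these were Ltbp2 (day 21 against day 14 C3H/HeJ) -0.01.

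Without each library in turn, the following changed sign, with their lowest and highest values. The range was for Acta2 (day 14 C57BL/6) -1.16 to 0.76, Pdgfra (day 14 C57BL/6) -0.34 to 0.18, Tcf21 (day 14 C57BL/6) -0.03 to 0.50, Mki67 (day 14 C57BL/6) -6.72 to 8.25, Col1a1 (day 21 C57BL/6) -0.54 to 0.54 and Col3a1 (day 21 C57BL/6) -0.53 to 0.43. The range was for Pdgfra (day 21 C57BL/6) -0.48 to 0.04, Tcf21 (day 21 C57BL/6) -0.46 to 0.21, Col1a1 (day 21 C3H/HeJ) -0.084 to 0.71, Tcf21 (day 21 C3H/HeJ) -0.22 to 0.12, Acta2 (day 14 KK/HlJ) -0.44 to 0.94 and Pdgfra (day 14 KK/HlJ) -0.94 to 0.76. The range was for Tcf21 (day 14 KK/HlJ) -0.40 to 0.21, Pdgfra (day 21 KK/HlJ) -0.084 to 1.08, Acta2 (day 14 mean) -0.39 to 0.25, Pdgfra (day 14 mean) -0.23 to 0.33, Tcf21 (day 14 mean) -0.12 to 0.092 and Ltbp2 (day 14 response C3H/HeJ against C57BL/6) -0.23 to 0.84. The range was for Postn (day 14 response KK/HlJ against C57BL/6) -0.61 to 0.36, Ltbp2 (day 14 response KK/HlJ against C3H/HeJ) -0.63 to 0.43, Postn (day 21 response KK/HlJ against C3H/HeJ) -0.39 to 0.57, Ltbp2 (day 21 against day 14 C3H/HeJ) -0.42 to 0.47, Postn (day 21 against day 14 KK/HlJ) -0.21 to 0.73 and endothelial (day 21 C3H/HeJ) -0.29 to 3.20. The range was for pericyte and smooth muscle (day 21 against day 14 C57BL/6) -1.33 to 0.23, cardiomyocyte (day 21 against day 14 C3H/HeJ) -0.41 to 1.29, oxidative phosphorylation (sham KK/HlJ against C57BL/6) -0.19 to 0.50 and cytosolic ribosomal proteins (sham KK/HlJ against C57BL/6) -0.15 to 0.78. Mki67, near the floor, ran over 0 to 8.20 (day 14 C3H/HeJ), 0 to 6.53 (day 21 C3H/HeJ) and 0 to 8.34 (day 21 KK/HlJ) and was at 0, with no sign, where the library with reads was left out. For pericyte and smooth muscle markers at day 14 in C57BL/6 the direction of the camera test, not of the median, changed without C57BL/6 ISO replicate 1, and the median ran from -1.60 to -0.054.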

Other observations

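The test of resting fibroblast genes, the offsets for length and GC content, leaving out the 4 divergent libraries, and the separate tests of C4b and of the other genes with a copy were chosen after results were seen; the other tests were written before.

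Within strains, camera with the preset correlation called some markers of other cell types, and none of the calls given here held with an estimated correlation. In C57BL/6 at day 14 the median of endothelial markers was -1.05 (camera adjusted p = 1.16e-05; 0.467 with an estimated correlation) and that of cardiomyocyte markers -0.89 (0.000627, and 0.467 with an estimated correlation). In C3H/HeJ at day 21 the median of endothelial markers was 2.34 (0.00115, and 0.6 with an estimated correlation), and -0.29 without ISO day 21 replicate 1. In KK/HlJ it was 0.95 at day 14 (0.00928, and 0.722 with an estimated correlation) and 1.33 at day 21 (0.00804, and 0.882 with an estimated correlation); the first call was lost without sham replicate 1 or ISO replicate 1 (adjusted p up to 0.194) and the second without sham replicate 1 or ISO replicate 2 (0.179). In KK/HlJ at day 14 the early-response genes Ier2 (-1.43) and Klf2 (-1.38) fell adjusted over the list alone, with 0 of that list passing over all genes in edgeR.

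Fits with the offsets, with DESeq2 and without the 4 divergent libraries all called the same 11 genes at day 14, 10 higher and 1 lower, of which 6 are the calls of the main test, and 5 genes at day 21. The day 14 additions, chosen after their values were seen, were Prg4 (1.40, edgeR adjusted p = 0.0583), Dkk3 (1.11, 0.0615), 1500015O10Rik (1.42, 0.121), Plod2 (1.38, 0.16) and the Notch target Heyl (-0.96, 0.121). In 6 of 6 day 14 ISO libraries Prg4, Dkk3 and 1500015O10Rik stood above both sham libraries of their strain, and Heyl below, while Plod2 stood above both in 5 and below both in 1.

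Activated fibroblast genes stood higher with ISO at both days. A larger share of fibroblasts alone would raise resting fibroblast genes alike, but their upper quartile was 0.12 at day 14 and 0.18 at day 21, against list medians of 1.11 and 0.70. Some resting genes, such as Hsd11b1 and Penk, fell at day 14. A fall of resting genes in activated cells could hide a rise, so a larger share together with such a fall is not ruled out. The median stayed at 1.11 and 0.72 with offsets for length and GC content, and at 1.24 and 1.09 without the 4 divergent libraries, which argues against these as the cause. A response of the cells to ISO may explain the pattern as a hypothesis, since batch and handling are not in the labels and were not tested.

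Other splits of the 12 libraries of each day into equal groups within strains were fitted with strain and treatment as terms, 100 of the 108 possible. For the list median, 1 of 100 splits, the real one, reached 1.1 at day 14 (highest other 0.77) and 1 of 100 reached 0.7 at day 21 (highest other 0.64). The real split was thus the most extreme of those drawn at each day, at day 21 by a narrow margin. The smallest share these draws can give is 1 of 100. Both days use the same sham libraries, so they are not independent. The libraries may be technical repeats and carry the structure described below, so chance is not excluded. For the count of genes, 3 of 100 splits gave at least the real 4 genes at day 14 (highest other 51) and 7 of 100 gave at least the real 1 gene at day 21 (highest other 37). Only 50 splits were drawn at first, with 3 of 50 as large at each day, and the draw was extended after that outcome was seen. Chance is therefore not excluded for the count of genes at either day. Splits that call 51 or 37 genes point to a structure of the samples. Both divide the libraries as the 2 sets of groups with patterned replicate correlations do, with replicate 1 of 1 set beside replicate 2 of the other. Both hold C57BL/6 sham replicate 2, C3H/HeJ sham replicate 1 and KK/HlJ sham replicate 1 on the same side. More genes were called along this structure than with ISO in these fits. What lies behind it stays open. In a check made after these counts were seen, the trends of libraries along GC content differed between the sides of these splits by 0.313 and 0.424 in rho, and 5 and 2 of 100 splits lay as far apart, while for transcript length 76 and 57 did. The split with the widest gap in GC trend at day 21 called 3 genes, and the day 14 split that called 11 genes had a gap that 53 of 100 reached.

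Among the 31 genes called between strains in sham libraries, 10 (32.3%) shared at least 50% of their 25-base words with another gene, against 3.7% of tested genes and 0 of the 9 genes called with ISO. The median absolute log2 ratio of the genes with a copy was 6.17, and that of their family totals was 1.43. C4b is an exception. Its log2 ratio was -2.55 in C3H/HeJ against C57BL/6 and 2.41 in KK/HlJ against C3H/HeJ. Its family total with C4a moved as far (-2.51 and 2.37, a median absolute ratio of 2.44), which argues against reads moved between these copies. Each of the C4b calls was lost without 3 of the 4 sham libraries compared, among them both of C3H/HeJ. For the 9 other genes the median of the family totals was 1.23. A gene near 0 summed with an expressed copy gives a smaller ratio whatever the cause. Gm8730, at 42.8 CPM in KK/HlJ sham and 0.229 CPM in C57BL/6 sham, lies in a family at 720 and 742 CPM. The smaller ratios thus cannot decide whether strain variants moved reads between copies. Some totals moved too. In C3H/HeJ against C57BL/6 the log2 ratio was 3.15 for the family of Gm13394 and 2.05 for that of Rps3a1. In KK/HlJ against C57BL/6 it was -0.08 for that of Rps26-ps1. Both moved reads and a difference between the strains stay open for these families. Such a difference also stays open for C4b and for the other 21 sham calls, whose own word share is below the threshold. Of these 21, Rps18 enters the test only as a copy in the family of Gm10260, and moved reads stay open for it. Rpl26 was not in the test of family totals. It stood at 175 and 196 CPM in C57BL/6 sham and at 0.393 and 1.26 CPM in C3H/HeJ sham. Lowered or moved reads stay open for it too, and for Hspa8, which was not in the test of family totals either.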
